A study of Homo sapiens with 4 samples.

How the data were processed

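The series holds 4 samples of total RNA from HCC70 cells, 1 for each combination of siRNA (siEGFP or siLRRC26, 10 nM) and time after transfection (48 h or 72 h). Per the labels' protocols, cells in 6-well plates were transfected with Lipofectamine RNAiMAX, the control siRNA came from Sigma and the LRRC26 siRNA from Dharmacon, so siRNA supplier and target cannot be told apart. RNA was amplified and labelled with Cy3 using a low-input Agilent kit. Per the labels' protocols it was treated with DNase on the column.

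The deposited files are the scanner software's output, 1 per array, and their values are intensity on a linear scale for each of 62976 spots. Per the file headers the authors used Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5. Per the file headers the processed signal was background-subtracted and detrended within each array and was not normalised between arrays, and the array annotation refers to human genome build hg19. The deposited value table of the series holds the same processed intensity: 100% of its values lay within 0.01 log2 of the scanner files on each array, with medians of 27.7, 24.5, 26.8 and 28.4 for siEGFP at 48 h, siLRRC26 at 48 h, siEGFP at 72 h and siLRRC26 at 72 h. Its scale is thus the linear processed signal.

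Control spots (4259 per array) and spots marked by the scanner software as non-uniform or population outliers (302, 235, 472 and 422 on the arrays in the same order) were left out. No gene spot was saturated (0 on each array). The main values were log2 of the processed signal minus each array's 75th percentile, taken over all probes because over 50% were well above background on every array, and spots of 1 probe were averaged. The percentile corresponded to signals of 286, 294, 322 and 305. All arrays came from 1 slide with 1 scan date, so slide and scan hold both siRNAs and both times and no batch term could be fitted. On 902 probes spotted 10 times, the median SD over spots was 0.071, 0.066, 0.072 and 0.073 on the log2 scale, and the 7 spike-in probes above a level of -2 differed between the siRNAs by at most 0.105 at 48 h and 0.090 at 72 h. These values cover spot-to-spot error only.

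The design was fixed before the data were examined and assumed a gene name column and a mean spot signal. The files have neither, so probes were named by matching their RefSeq accession, without version, to a RefSeq table of assembly GRCh38.p14, which served for names only, and normexp was run on the median spot signal. Of 50599 probes 28174 matched 1 symbol, for 20503 symbols in all, and the 22425 others were kept as unnamed transcripts. Coordinates were not used here. A probe counted as detected where it was well above background on at least 2 of the 4 arrays, and a gene was represented by its detected probe with the highest mean level. This left 23545 genes and unnamed transcripts, 15297 of them with a symbol.

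Differences were tested with limma 3.58.1 in R 4.3.3, with an additive fit of siRNA and time over the 4 arrays, eBayes moderation and Benjamini-Hochberg adjustment at 0.05. The fit leaves 1 residual degree of freedom, which is the siRNA-by-time interaction, so its p-values measure how alike the 2 times are and not the spread between cultures. Counts by size used a 2-fold difference at each time. Where a gene was not well above background on 1 of 2 arrays compared, its fold is given as a bound ("at least"), the brighter value over the higher of the dim array's lowest signal among probes well above background and the probe's own signal. Simulations on 23545 genes used a spread set by level, a trend of the fit's residual variance scaled to its mean. All genes of 1 level thus had the same spread, which includes the siRNA-by-time interaction. At this spread the siRNA test recovered 0 of 200 genes changed by 2-fold and 0 of 200 changed by 4-fold. With the spread divided by 10 it recovered 199 and 200 of 200, with 2 and 3 false calls. limma's camera gave a p of 8.55e-09 for a simulated list of 30 genes shifted by -0.30 and 0.503 for a list left alone. The simulated genes varied independently and each list was drawn 1 time. This does not test lists whose members move together, nor the rate of false calls.

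Before the data were examined, 31 gene lists were fixed from general knowledge: BK channel subunits, NF-kB target genes, mesenchymal genes, epithelial adhesion and identity genes, proteases and inhibitors of invasion, integrins and focal adhesion, basal breast genes, luminal breast genes, G1/S and DNA replication genes, G2/M and mitosis genes, interferon-stimulated genes, antigen presentation genes, p53 target genes, apoptosis regulators, unfolded protein and integrated stress response genes, heat shock genes, hypoxia genes, cholesterol synthesis genes, fatty acid synthesis genes, respiratory chain genes, ribosomal protein genes, small RNA pathway genes, immediate early genes, TGF-beta target genes, Wnt target genes, stem cell-associated genes, lysosome and autophagy genes, housekeeping genes, and fibroblast, leukocyte and endothelial markers. The 28 lists with at least 5 detected members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each list median was also ranked among 10000 random lists of the same size matched on level. Random lists and camera take genes as the units, so neither measures the spread between cultures. Some genes belong to more than 1 list.

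The genes named in the text were chosen by a rule written before the data were examined. They are LRRC26 and the detected BK channel subunits, the 12 highest and 12 lowest genes by the smaller of their 2 absolute siRNA differences (same direction at both times, at least 3 arrays detected, an established gene symbol), up to 4 members of each list by the same measure, the 6 highest and 6 lowest genes by time, and the 4 genes whose siRNA difference rose most and the 4 for which it went down most, detected on all 4 arrays. Members of the 4 lists added later are named outside this rule. Other genes are named only where the text says so.

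The alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation of the processed signals, the value table, detection on all 4 arrays, no detection filter, a 75th percentile over probes detected on all 4 arrays, the mean over a gene's probes, a floor at each array's lowest detected signal, a prior variance with an intensity trend, no time term, an adjusted p under 0.1, a 1.5-fold threshold and an estimated inter-gene correlation. Quantile normalisation of the processed signals, both detection filters, the other percentile, the mean over probes and the floor were planned for the gene counts and were extended to the gene lists after the data were seen. The estimated inter-gene correlation rests on the fit's 1 residual degree of freedom and could hardly call any list. A list that failed with it is thus not shown to be unshifted, and the preset correlation is an assumed value.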

Results

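Gene expression was measured in HCC70, an established human triple-negative breast cancer cell line, after transfection of 10 nM siRNA. The siRNA against LRRC26 (siLRRC26) was compared with an siRNA against EGFP (siEGFP), a jellyfish-derived reporter that served as the control target. LRRC26 encodes a leucine-rich repeat membrane protein known as an auxiliary subunit of BK potassium channels. RNA was taken 48 h and 72 h after transfection and hybridised to 1-colour Agilent arrays. There was 1 array for each siRNA and time, so no group had a replicate. Of 50599 probes, 61.1% were well above background on the siEGFP array at 48 h and 58.5% on the siLRRC26 array at 48 h, against 51.4% and 52.3% at 72 h. Probes for 23545 genes or unnamed transcripts were well above background on at least 2 arrays, and 19547 of these were so on all 4 arrays. Differences are given on the log2 scale as siLRRC26 minus siEGFP, at 48 h first and at 72 h second unless stated otherwise.

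LRRC26 itself was lower in the siLRRC26 cultures at both times. Its difference was -0.60 at 48 h and -0.59 at 72 h, or 1.52-fold and 1.51-fold lower, which left 65.9% and 66.3% of the control level. The gene was read by 1 probe, well above background on all 4 arrays, and the scanner error of each difference was 0.20. Among the 1000 genes closest to LRRC26 in level, 2 differed by as much in this direction at 48 h, 8 at 72 h and 1 at both times. The additive limma fit over the 4 arrays gave a mean difference of -0.60 (SE 0.11) with an adjusted p of 0.815, and the adjusted p ranged from 0.0216 to 1.00 over the alternative settings. Of the other BK channel subunits, KCNMB1, KCNMB3 and KCNMB4 were detected, with differences of -0.26 and -0.0098, 0.11 and -0.16, and -0.11 and -0.12. A further probe of KCNMB3 gave -0.33 and -0.99. The pore-forming subunit KCNMA1 and LRRC38, LRRC52, LRRC55 and KCNMB2 were not detected on 2 or more arrays.

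**Figure D1:**
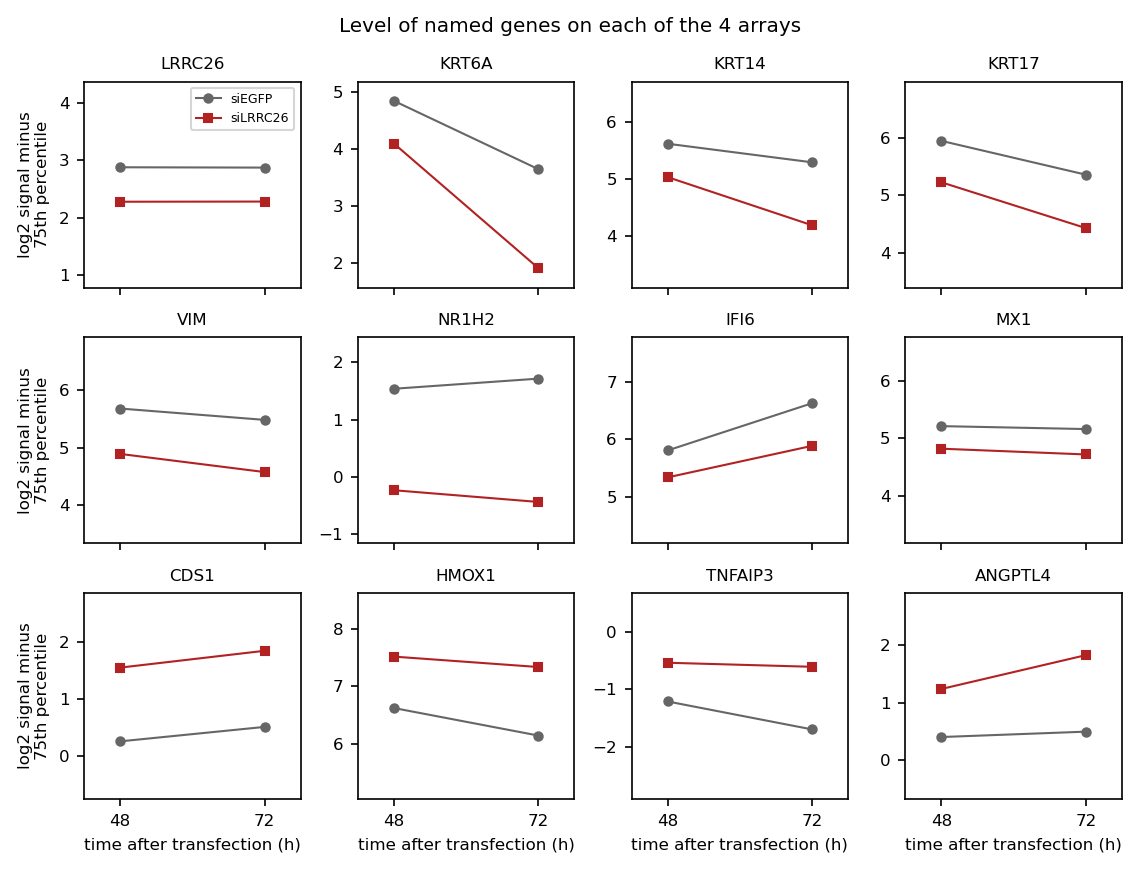
Level of 12 named genes on each of the 4 arrays, as log2 signal minus the array's 75th percentile, against time after transfection in hours; each point is 1 array (grey circles siEGFP, red squares siLRRC26), lines join the arrays of 1 siRNA and every panel spans the same log2 range. LRRC26 lies 0.60 and 0.59 lower with siLRRC26, NR1H2 3.42-fold and 4.45-fold lower, and CDS1 1.29 and 1.33 higher.

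The comparison of siLRRC26 with siEGFP asks which transcripts differ between cultures given these siRNAs. LRRC26 was only partly reduced, and with 1 siRNA per target the differences cannot be assigned to it. The transcripts that stood lowest with siLRRC26 included NR1H2, which encodes the liver X receptor beta, at -1.77 and -2.16 (3.42-fold and 4.45-fold lower), and SCEL, which encodes sciellin of the cornified envelope, at -1.21 and -1.64. KRT80, an epithelial keratin, was at -0.88 and -1.01. Those that stood highest included CDS1, a CDP-diacylglycerol synthase, at 1.29 and 1.33 (2.44-fold and 2.51-fold higher), its paralog CDS2 at 0.94 and 0.92, and HMOX1, the inducible haem oxygenase, at 0.90 and 1.20. No single transcript passed the test across all genes (below), so these are differences by size, alike in direction at both times.

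Of the 12 genes that ranked highest, 8 were well above background on all 4 arrays. Besides CDS1, CDS2 and HMOX1 these were RND1 2.15-fold and 2.64-fold higher, BMF, a pro-apoptotic BCL2-family member, at 0.95 and 1.07, BHLHE41 at 0.95 and 1.03, LYPLA1 at 0.92 and 1.20, and ZFP91 at 0.91 and 1.08. The other 4 were well above background on 3 arrays and had only a bound at the time where siEGFP was dim. ARSL was 5.48-fold higher at 48 h and at least 1.68-fold higher at 72 h, TGM2 2.78-fold and at least 2.61-fold, and BAIAP3 1.84-fold and at least 2.39-fold. SPN was at least 2.54-fold higher at 48 h and 1.91-fold at 72 h. Further probes of CDS1 (1.20 and 0.63), LYPLA1 (1.05 and 0.70) and ZFP91 (0.84 and 0.52) had the same direction. A further probe of TGM2 did not (0.85 and -0.84), nor did one of BMF (-0.22 and 1.82).

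Of the 12 genes that ranked lowest, 7 were well above background on all 4 arrays. Besides NR1H2, SCEL and KRT80 these were TMEM214 at -1.13 and -0.90, NECAP1 at -1.07 and -0.93, POGLUT2 at -0.91 and -0.95, and CFAP58 at -0.89 and -1.02. NECAP1 was also lower on a further probe, at -0.56 and -0.60. The other 5, of which 4 are given here, were not well above background on the siLRRC26 array at 72 h. CHST11 was 2.05-fold lower at 48 h and at least 1.73-fold lower at 72 h, ALOX15 2.01-fold and at least 3.79-fold, CMTM2 1.92-fold and at least 1.71-fold, and GCM2 1.87-fold and at least 2.10-fold.

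By size, 13 genes were at least 2-fold higher and 37 at least 2-fold lower with siLRRC26 at both times, while 123 were at least 2-fold different in opposite directions. At 48 h 63 genes were at least 2-fold higher and 288 lower, and at 72 h 964 were higher and 433 lower. Among the 19547 genes well above background on all 4 arrays the counts were 3 higher, 4 lower and 2 opposite at both times, 16 higher and 52 lower at 48 h, and 139 higher and 92 lower at 72 h. The differences at the 2 times correlated across genes with r = -0.039 over all genes and r = 0.17 over those on all 4 arrays, where genes are not independent replicates. The median difference of all genes was -0.053 at 48 h and 0.035 at 72 h. Among genes with a mean level of -4 or below it was -0.24 and 0.35, and above 4 it was -0.047 and 0.024. The surplus of lower genes at 48 h and of higher genes at 72 h went the way dim genes shifted as a group.

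limma called 0 genes higher and 0 lower with siLRRC26 at an adjusted p under 0.05. The lowest adjusted p was 0.815, and 1243 genes had an unadjusted p under 0.05, where 1177 of 23545 would by chance. The fit has 1 residual degree of freedom, which is the siRNA-by-time interaction. On simulated data with a spread set by level from this fit it recovered 0 of 200 genes changed by 4-fold. With normexp background correction and quantile normalisation, which pull dim spots together, limma called 60 genes higher and 81 lower, among them 9 of the 12 named higher genes, 7 of the 12 named lower genes and LRRC26.

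**Figure D2:**
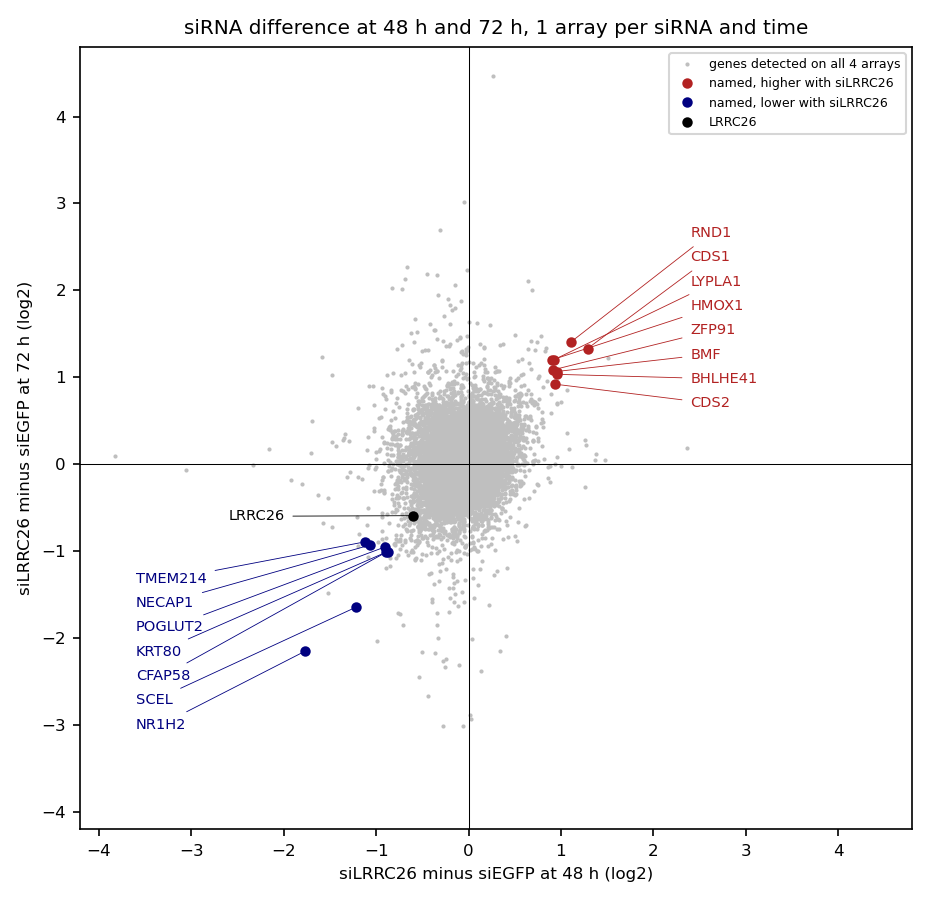
Difference between siLRRC26 and siEGFP at 48 h (x axis, log2) and at 72 h (y axis, log2), with 1 grey point for each of the 19547 genes well above background on all 4 arrays. The 8 named higher genes (red) and 7 named lower genes (blue) of this set lie in the upper right and lower left, beyond LRRC26 (black) at -0.60 and -0.59, and PHKA1 at -3.83 and 0.096 and CTAGE10P at 0.26 and 4.47 lie near the axes.

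The basal breast genes shifted lower with siLRRC26. Of 20 detected members, 12 were lower at both times and 1 was higher. The list medians were -0.24 and -0.32, below all of 10000 random lists matched on level. Genes that move together can shift between any cultures, so here and below these ranks and camera's p-values do not measure that spread. The adjusted p by limma camera was 0.00227 at the preset inter-gene correlation and 0.937 with an estimated correlation. The estimate rests on 1 residual degree of freedom and could hardly call any list, so it decides neither way, here and for the lists below. The basal keratins KRT6A (-0.75 and -1.73), KRT17 (-0.72 and -0.93), KRT14 (-0.58 and -1.10) and KRT6B (-0.45 and -0.85) led the list, and the 2 other KRT14 probes were also lower (-0.37 and -0.68, -0.33 and -0.75). No member passed limma's test, adjusted over the list alone or over all genes, and 5 members were called lower with normexp.

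The interferon-stimulated genes also shifted lower: 24 of 37 detected members were lower at both times and 4 were higher, with medians of -0.14 and -0.28, at the 0.01 and 0 percentiles of random lists. The adjusted p by limma camera was 0.00135, and 0.937 with an estimated correlation. IFI6 stood at -0.47 and -0.75, IFI44L at -0.38 and -0.70, OAS2, an RNA sensor of the oligoadenylate synthetase family, at -0.51 and -0.38, and MX1, an antiviral GTPase, at -0.39 and -0.44. The antigen presentation genes shifted lower too, with 10 of 20 members lower at both times and 3 higher, medians of -0.074 and -0.18, at the 25.2 and 0.05 percentiles of random lists. The adjusted p by limma camera was 0.0460, and 0.937 with an estimated correlation. Here the transporters of antigenic peptides TAP2 (-0.56 and -0.55) and TAP1 (-0.30 and -0.50), the transactivator NLRC5 (-0.81 and -0.44) and HLA-B (-0.23 and -0.26) were the members farthest from 0 at both times.

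The apoptosis regulators shifted higher, with 15 of 25 members higher at both times and 6 lower and medians of 0.048 and 0.11, at the 90.8 and 96.1 percentiles of random lists. The adjusted p by limma camera was 0.0460, and 0.937 with an estimated correlation. The list holds genes that promote and genes that restrain cell death. The members farthest from 0 were BMF, BAK1 (0.38 and 0.28) and BBC3 (0.23 and 0.41), which promote it, and BCL2L2 (-0.28 and -0.33), which restrains it. The basal and interferon shifts passed under the 8 alternatives with a preset correlation. The antigen presentation and apoptosis shifts ended with quantile normalisation of the processed signals (adjusted p = 0.0844 for each), with no detection filter (0.0790 and 0.0797) and with the mean over probes (0.0539 and 0.0698).

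The mesenchymal genes did not pass (10 of 24 lower at both times and 3 higher, medians -0.18 and -0.067, adjusted p = 0.0585, and from 0.0276 to 0.937 over the alternatives). Of its members, VIM, which encodes the intermediate filament vimentin, was at -0.79 and -0.91, the fibronectin receptor subunit ITGA5 at -0.51 and -1.10, LOX at -0.51 and -0.81 and TAGLN at -0.52 on both occasions. The epithelial adhesion and identity genes had 9 members lower and 9 higher of 29 (medians 0.010 and -0.031, adjusted p = 0.914), with the P-cadherin gene CDH3 at 0.59 and 0.27 and CLDN1 at -0.49 and -0.26. Among 25 integrin and focal adhesion genes 12 were lower and 8 higher (medians -0.0056 and -0.20, adjusted p = 0.491, and from 0.0342 with normexp to 0.937 over the alternatives), with ITGA2 at 0.44 and 0.94 and FLNA at -0.33 and -0.62. The proteases and inhibitors of invasion were 10 lower and 9 higher of 28 (medians -0.0040 and 0.027, adjusted p = 0.906). RECK, a membrane-anchored inhibitor of matrix metalloproteinases, was at 0.89 and 0.81 but at 0.31 and -0.013 on a further probe. The 25 luminal breast genes were 9 lower and 9 higher (medians -0.0065 and 0.042, adjusted p = 0.491), with the luminal transcription factor genes GATA3 at 0.27 and 0.28, FOXA1 at 0.24 and 0.29 and SPDEF at 0.28 and 1.07.

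The NF-kB target genes were 12 lower and 17 higher of 32 (medians 0.066 and 0.078, adjusted p = 0.337). The medians lay at the 99.15 and 90.07 percentiles of random lists, so the list leaned higher without passing. With normexp limma called 3 members higher and 1 lower, and members went both ways. TNFAIP3, a feedback inhibitor of NF-kB, was at 0.68 and 1.09 and the chemokine gene CXCL2 at 0.63 and 0.70, whereas the chemokine gene CCL2 was at -0.73 and -0.81 and VCAM1 was at least 1.74-fold lower at 48 h and 3.44-fold lower at 72 h. The hypoxia genes were 4 lower and 9 higher of 24 (medians 0.048 and 0.11, adjusted p = 0.369), led by ANGPTL4, an inhibitor of lipoprotein lipase, at 0.84 and 1.34 and PFKFB3 at 0.60 and 0.52, while ADM was at -0.43 and -0.34. A further probe of PFKFB3 gave -0.028 and 0.21. The immediate early genes were 5 lower and 6 higher of 23 (medians 0.0066 and 0.0020, adjusted p = 0.492), with ZFP36 at 0.16 and 0.82. The TGF-beta target genes were 5 lower and 10 higher of 23 (medians 0.085 and 0.051, adjusted p = 0.491). CCN2 was at -0.58 and -0.35 and CDKN2B at -0.28 and -0.31, whereas SKIL was at 0.28 and 0.56 and ID3 at 0.24 and 0.28. The Wnt target genes were 6 lower and 2 higher of 12 (medians -0.034 and -0.070, adjusted p = 0.492), with AXIN2, a feedback inhibitor of the pathway, at 0.67 and 0.51.

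Genes of the cell cycle lay near 0. The G1/S and DNA replication genes were 8 lower and 8 higher of 31 (medians 0.061 and -0.043). The G2/M and mitosis genes were 5 lower and 9 higher of 35 (medians 0.050 and -0.037), with an adjusted p of 0.491 for each. The p53 target genes were 9 lower and 10 higher of 24 (medians 0.0032 and -0.00095, adjusted p = 0.914). GADD45A was at -0.49 and -0.39 and CDKN1A at -0.22 and -0.39, whereas TRIAP1 was at 0.26 and 0.40 and BBC3 at 0.23 and 0.41. The unfolded protein and integrated stress response genes were 7 lower and 10 higher of 30 (medians -0.030 and 0.074, adjusted p = 0.491). The heat shock genes were 8 lower and 6 higher of 19 (medians -0.023 and 0.051, adjusted p = 0.914). The stem cell-associated genes were 4 lower and 4 higher of 16 (medians 0.019 and -0.036, adjusted p = 0.914), with CD44 at -0.43 and -0.19 (a further probe -0.019 and 0.093) and CD24 at -0.23 and -0.32.

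Among metabolic lists, the cholesterol synthesis genes were 10 lower and 6 higher of 24 (medians -0.018 and -0.064, adjusted p = 0.491), with HMGCS1 at -0.38 and -0.35. The fatty acid synthesis genes were 9 lower and 3 higher of 18 (medians -0.028 and -0.087, adjusted p = 0.369) with FADS1 at -0.23 and -0.39. The respiratory chain genes were 5 lower and 10 higher of 29 (medians -0.0085 and 0.090, adjusted p = 0.491). The lysosome and autophagy genes were 6 lower and 9 higher of 27 (medians -0.015 and 0.065, adjusted p = 0.492) with CTSZ at -0.51 and -0.85. The ribosomal protein genes were 11 lower and 1 higher of 32 (medians -0.10 and 0.023, adjusted p = 0.491). The small RNA pathway genes were 2 lower and 5 higher of 13 (medians -0.027 and 0.16, adjusted p = 0.309), with TNRC6A at 0.40 and 0.37. The housekeeping genes were 4 lower and 7 higher of 15 (medians 0.013 and 0.059, adjusted p = 0.491), with TBP at -0.30 and -0.29 and IPO8 at 0.29 and 0.28. Markers of other cell types did not set the siRNAs apart: the leukocyte markers were 3 lower and 1 higher of 10 (medians -0.11 and 0.16, adjusted p = 0.914), and only 4 fibroblast markers (medians -0.062 and 0.13) and 4 endothelial markers (medians -0.040 and 0.0067) were detected, too few for a test. These adjusted p are limma camera's over 28 lists. The direction of the camera test differed from the sign of the list mean for the protease, p53, heat shock and stem cell lists, whose adjusted p was 0.906 or higher.

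**Figure D3:**
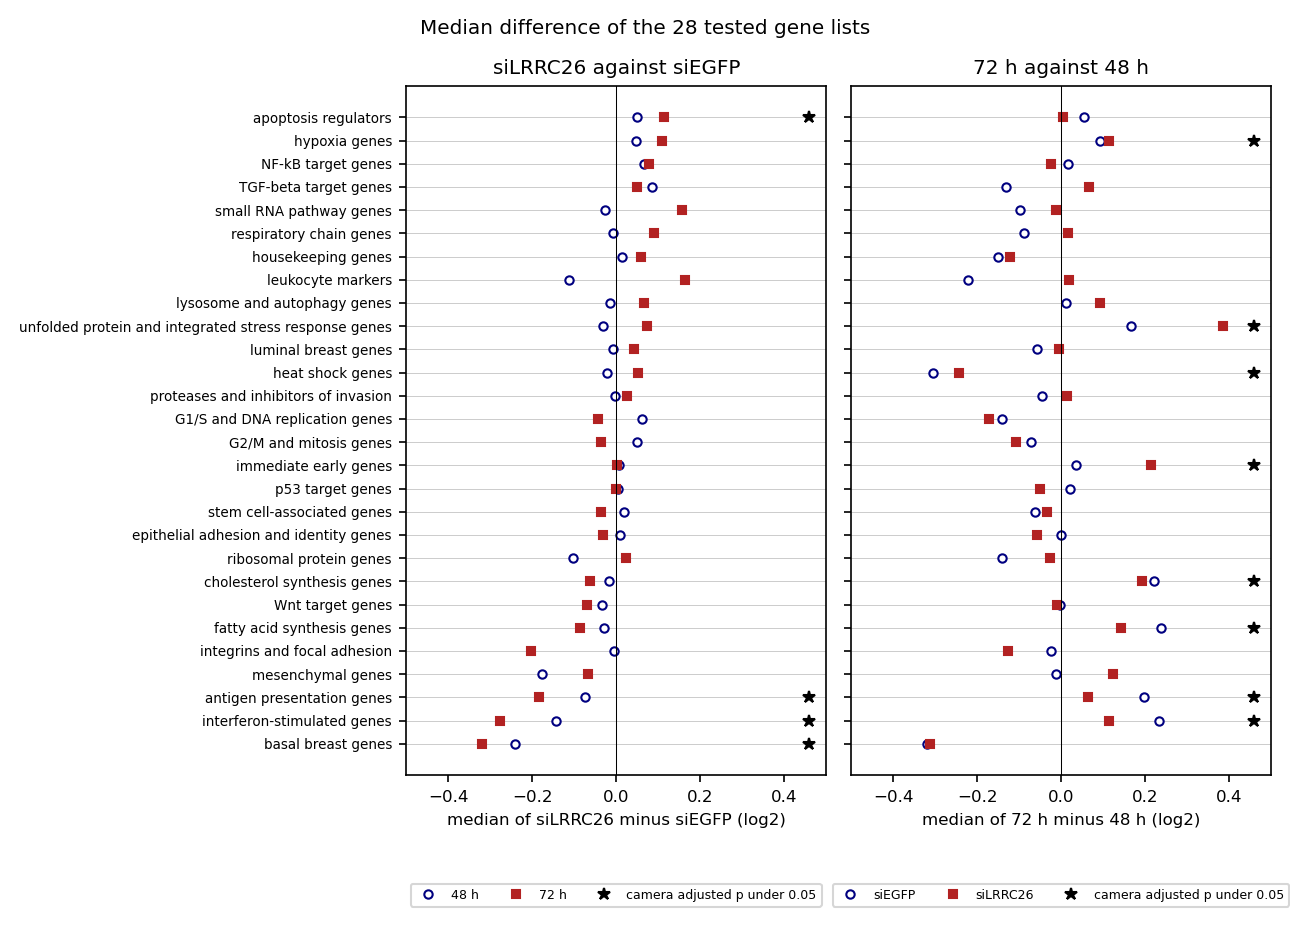
Median difference (log2) of the 28 tested gene lists between siLRRC26 and siEGFP at 48 h (open circles) and 72 h (red squares), left, and between 72 h and 48 h in siEGFP (open circles) and siLRRC26 (red squares), right; stars mark lists with a limma camera adjusted p under 0.05 at the preset correlation. Stars mark 4 lists on the left, with basal breast genes lowest at -0.24 and -0.32, and 8 lists on the right.

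The comparison of 72 h with 48 h, the other factor of the design, is given as 72 h minus 48 h in siEGFP first and in siLRRC26 second. Stress response and lipid synthesis genes shifted higher over this time. Of 30 unfolded protein and integrated stress response genes 21 were higher with both siRNAs and 1 was lower, with medians of 0.17 and 0.39. The adjusted p by limma camera was 1.00e-08, and 0.778 with an estimated correlation. Members were CHAC1, a glutathione-degrading enzyme, at 0.83 and 0.55 and EDEM1 at 0.47 in each. Of 24 cholesterol synthesis genes 19 were higher with both and 1 lower (medians 0.22 and 0.19, adjusted p = 8.04e-07), and of 18 fatty acid synthesis genes 13 were higher and 2 lower (medians 0.24 and 0.14, adjusted p = 0.000113), with ACSS2 at 0.83 and 0.20 and FADS1 at 0.55 and 0.39. The heat shock genes shifted lower, with 15 of 19 lower with both and 1 higher (medians -0.31 and -0.24, adjusted p = 0.00772), including the HSP90 co-chaperone gene FKBP4 at -0.44 and -0.50. With an estimated correlation the adjusted p was 0.796 for the fatty acid list and 0.778 for the other lists of this paragraph.

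The interferon-stimulated genes shifted higher with time, with 23 of 37 higher with both siRNAs and 2 lower (medians 0.23 and 0.12, adjusted p = 8.04e-07), and IFI6 stood at 0.83 and 0.55. The antigen presentation genes (11 of 20 higher and 4 lower, medians 0.20 and 0.064, adjusted p = 0.0183), the immediate early genes (12 of 23 higher and 7 lower, medians 0.037 and 0.21, adjusted p = 0.0267) and the hypoxia genes (11 of 24 higher and 5 lower, medians 0.093 and 0.11, adjusted p = 0.0486) also shifted higher by limma camera. With an estimated correlation the adjusted p of these 4 lists was 0.778. The basal breast genes had 12 of 20 members lower with both siRNAs and 3 higher (medians -0.32 and -0.31), with KRT6A at -1.19 and -2.18 and KRT17 at -0.59 and -0.80, and the G1/S and DNA replication genes 21 of 31 lower and 4 higher (medians -0.14 and -0.17). These 2 lists did not pass with the main values (adjusted p = 0.0529 and 0.0693) but did in 5 and 4 of 9 alternatives. The 18 others did not pass with the main values (adjusted p from 0.0950 to 0.975). The median of all genes was -0.11 in siEGFP and -0.024 in siLRRC26.

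Among single genes that ranked highest at 72 h with both siRNAs were RASGRP2, a guanine nucleotide exchange factor, at 2.94 and 2.37. Others were FAM171A1 at 1.94 and 1.86, GPM6B at 1.64 and 2.30 and SLCO4C1 at 1.40 and 1.71, all well above background on the 4 arrays. The endothelial adhesion molecule gene VCAM1 was 6.19-fold higher in siEGFP and at least 3.13-fold higher in siLRRC26, and FAM74A1 4.90-fold and at least 7.81-fold higher. Further probes of RASGRP2 (-0.53 and 0.23, -0.29 and 0.48), FAM171A1 (-0.15 and 1.46) and GPM6B (-0.73 and 0.10) went another way in siEGFP. Among those that ranked lowest were GPX2, a glutathione peroxidase, at -1.30 and -1.53, the cornified envelope gene SPRR1B at -1.27 and -1.86, KRT6A, TAGLN at -1.05 in each, IGFL1 at -1.32 and -1.02, and ARSL, which was at least 1.12-fold lower in siEGFP and 3.65-fold lower in siLRRC26.

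The time changes correlated across genes with r = 0.21 over all genes and r = 0.39 over those on all 4 arrays. Over all genes 76 were at least 2-fold higher and 174 at least 2-fold lower with both siRNAs, against 184 in opposite directions. Among genes well above background on all 4 arrays the counts were 29 higher, 19 lower and 1 opposite, so the surplus of lower and opposite genes lay among dim genes. limma called 0 genes at 72 h against 48 h (lowest adjusted p 0.398, 2781 genes at an unadjusted p under 0.05), and 477 higher and 279 lower with normexp, including the 6 named higher and 6 named lower genes. These named genes too were chosen on the same arrays for changes with both siRNAs, so the overlap is no separate support. With no detection filter, of these 8 lists only the stress response and heat shock lists still passed. The hypoxia and immediate early shifts also ended with genes on all 4 arrays (adjusted p = 0.101 and 0.0522) and with a signal floor (0.125 and 0.0694).

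The siRNA difference of some genes changed in size from 48 h to 72 h, by a value that no test supports since each rests on 1 array. Among genes well above background on all 4 arrays, the difference rose most for PHKA1, which encodes a phosphorylase kinase subunit (-3.83 to 0.096), CTAGE10P (0.26 to 4.47), DOCK5 (-0.31 to 2.69) and FAM225A (-0.66 to 2.27). It went down most for APOA1 (-0.27 to -3.02), MYOG (-0.43 to -2.67), CCPG1 (2.37 to 0.19) and HBQ1 (-0.25 to -2.24). For each of these 8 genes 1 array stood apart from the other 3. The siEGFP array at 48 h was high for PHKA1 and low for CCPG1, the siLRRC26 array at 72 h was high for CTAGE10P, DOCK5 and FAM225A, and the siEGFP array at 72 h was high for APOA1, MYOG and HBQ1. Further probes gave 0.0018 and -0.20 for PHKA1, 0.16 and -0.28 for CTAGE10P, and 0.067 and -0.34 for DOCK5.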

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

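The test of dim signal in this part, with its bright genes, and the split at a mean level of -2 were chosen after the result was seen. Each gene and list flagged here stood out because siLRRC26 lay on opposite sides of siEGFP at the 2 times. The wide differences at 72 h were taken up for their size, after they were seen. No difference between the times was tested, since each time has 1 array per siRNA.

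PHKA1 went from -3.83 at 48 h to 0.096 at 72 h, a change of 3.93, DOCK5 from -0.31 to 2.69, a change of 3.00, and FAM225A from -0.66 to 2.27, a change of 2.93. For each of these genes 1 array stood apart from the others. Further probes of PHKA1 (0.0018 and -0.20) and DOCK5 (0.067 and -0.34) did not follow.

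The list medians that changed sign from below 0 to above 0 rose by 0.28 for the leukocyte markers, 0.18 for the small RNA pathway genes, 0.13 for the ribosomal protein genes, 0.10 for the unfolded protein and integrated stress response genes, 0.099 for the respiratory chain genes, 0.081 for the lysosome and autophagy genes, 0.074 for the heat shock genes, 0.048 for the luminal breast genes and 0.031 for the proteases and inhibitors of invasion. Those that changed from above 0 to below 0 moved by -0.10 for the G1/S and DNA replication genes, -0.086 for the G2/M and mitosis genes, -0.055 for the stem cell-associated genes, -0.041 for the epithelial adhesion and identity genes and -0.0042 for the p53 target genes. The median of all genes moved from -0.053 to 0.035 between the same times. Dim genes moved more, from -0.24 to 0.35 at a mean level of -4 or below and from -0.20 to 0.15 at -4 to -3. Above a level of 4 the median went from -0.047 to 0.024. A change of a list with dim members is thus not shown to be particular to it.

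The siRNA differences at 72 h were wide: 964 genes were at least 2-fold higher and 433 lower, against 63 and 288 at 48 h. Of the genes at least 2-fold different, 80.6% at 48 h and 83.5% at 72 h were not well above background on all 4 arrays, against 17.0% of all genes tested, so dim genes made up most of both counts. Dim genes as a group also shifted lower at 48 h and higher at 72 h, the direction of each surplus. Signal near the background is argued against as the whole cause of the wider differences at 72 h. Among the 2440 genes with a mean level above 4, the SD of the differences at 72 h was 1.497 times that at 48 h (95% bootstrap bounds 1.42 and 1.58), against 1.64 times over all genes. Among genes well above background on all 4 arrays, 139 were at least 2-fold higher and 92 lower at 72 h, against 16 and 52 at 48 h. The cause of the wider differences stays open, as each time has 1 array per siRNA. Among the 15492 genes with a mean level above -2, 79 were at least 1.5-fold different in the same direction at both times and 3 in opposite directions, with r = 0.28 across genes. Among the 8053 dimmer genes the counts were 227 and 486, with r = -0.094. PHKA1, DOCK5 and FAM225A are detected on all 4 arrays. PHKA1 has a mean level above -2, while DOCK5 and FAM225A belong to the dimmer genes. No biological explanation was tested for them.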

How the results depend on the processing

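The alternatives were planned before the data were examined, except that 6 of the 9 applied to the gene lists (quantile normalisation of the processed signals, both detection filters, the other percentile, the mean over probes and the floor) were added for the lists after the data were seen. All of those fixed beforehand were run. No paired analysis was possible because each group has 1 array and time is already a term of the fit. LRRC26 kept its direction under every alternative, from -0.61 to -0.59, with 48 h alone (-0.60) and 72 h alone (-0.59), and no called list changed direction, nor did any of the 24 genes named by siRNA difference or the 12 named by time. Other genes in the text were compared with normexp alone or with no alternative. Of the alternative values for the comparisons, 83 kept the main result, 22 were stronger, 23 weaker and 4 moved. Signal over background limits the counts by size, which fell with genes detected on all 4 arrays and, at both times together and at 72 h, with a floor. They also fell with normexp, which changes the normalisation too, and they rose with a lower fold threshold. The cause of the other changes was not tested.

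With normexp and quantile normalisation limma called 60 genes higher and 81 lower with siLRRC26 and 477 higher and 279 lower at 72 h, and LRRC26 was called at -0.59 (adjusted p = 0.0216). At least 2-fold were 1 gene higher and 3 lower at both times, 6 and 13 at 48 h, and 55 and 59 at 72 h, and the correlation of the 48 h and 72 h differences moved to 0.20. With an intensity trend in the prior variance limma called 1 gene higher and 2 lower with siLRRC26, and 23 higher and 8 lower at 72 h. With quantile normalisation of the processed signals about 1.1e+02 genes were at least 2-fold higher and 173 lower at 48 h, the correlation was 0.011, and 2 lists shifted with siLRRC26.

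With genes detected on all 4 arrays, 3 genes were higher and 4 lower at both times, 16 and 52 at 48 h, and 139 and 92 at 72 h, with a correlation of 0.17. With no detection filter the counts were 134 and 204 at both times, 921 and 3076 at 48 h, and 3503 and 1506 at 72 h, while 2 lists shifted with siLRRC26 and 4 with time (the stress response, heat shock, basal breast and G1/S lists). With a floor they were 5 and 18 at both times and 388 and 253 at 72 h, with a correlation of 0.032. At 1.5-fold they were 93 and 213 at both times, 250 and 1320 at 48 h, and 2109 and 1142 at 72 h. With the mean over a gene's probes 2 lists shifted with siLRRC26. With an estimated correlation, which could hardly call any list on 1 residual degree of freedom, 0 lists passed with siLRRC26 and 0 with time.

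Of the gene list values, 463 stayed on their side of the threshold, 13 passed it and 28 no longer did. The mesenchymal genes passed in 2 of 9 alternatives (adjusted p from 0.0276 to 0.937) and the integrin and focal adhesion genes in 1, normexp (adjusted p from 0.0342 to 0.937). With time the basal breast genes shifted in 5 of 9 (adjusted p from 0.000202 to 0.796), the G1/S and DNA replication genes in 4 (adjusted p from 0.0118 to 0.778) and the lysosome and autophagy genes in 1 (adjusted p from 0.0448 to 0.979). For the named genes 28 values passed the threshold, each with normexp, and 248 were unaltered in this respect.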

Other observations

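The tests of keratin probes and of the siRNAs as transfected RNA, and limma camera on the 4 added lists, were chosen after the results were seen. The tests of progression with time and of the target genes of NR1H2, NRF2 and PPAR and of squamous differentiation were written before their values were seen, on genes prompted by the named results.

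PPARA, ANGPTL4 and PDK4 were higher with siLRRC26; PPARA and PDK4 are named here after their values were seen. PPARA, a nuclear receptor for fatty acids, stood at 1.07 and 0.85 at 48 h and 72 h, ANGPTL4 at 0.84 and 1.34, and PDK4, a kinase that restrains pyruvate dehydrogenase, at 0.71 and 1.32. All 3 were called higher by limma with normexp (adjusted p = 0.0101, 0.00335 and 0.0339) and none with the main values. Of 18 other detected PPAR target genes, 8 were higher at both times and 2 lower, among them the mitochondrial carnitine carrier gene SLC25A20 (0.43 and 0.40), PEX11A (0.36 and 0.35), CPT1A (0.27 and 0.31) and ACADM (0.16 and 0.45). Their medians of 0.088 and 0.22 lay above 98.2% and 99.7% of random lists. By limma camera over the 4 added lists the adjusted p was 0.0151 at the preset correlation and 0.476 with an estimated correlation. The estimate rests on 1 residual degree of freedom and could hardly call any list, so it decides neither way. Whether a higher PPAR programme accompanies siLRRC26 stays open with 1 array per siRNA and time. The list was 1 of 4 added lists and was prompted by the values of PPARA, ANGPTL4 and PDK4, which it leaves out.

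LRRC26 was not the gene that differed most. Of 19547 genes well above background on all 4 arrays, 70 were lower than LRRC26 at both times, 46 were higher than its mirror value at both times and 41 exceeded both sizes in opposite directions. NR1H2 was 3.42-fold and 4.45-fold lower where LRRC26 was 1.52-fold and 1.51-fold lower. The siRNA sequences are not given in the sources used here, so matches of their seeds to these transcripts were not tested.

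The 12 detected LXR target genes had medians of -0.096 and 0.0032, which lay at the 18.5 and 40.0 percentiles of random lists, so a drop of the list as a whole with NR1H2 was not seen. Of these genes 5 were lower at both times, among them ABCG1 (-0.35 and -0.66) and FASN (-0.13 and -0.37), and 3 were higher, so a drop of some LXR targets stays open. The squamous differentiation genes outside the basal list, tested because SCEL and KRT80 were low, had medians of -0.023 and -0.095 over 29 genes, at the 57.6 and 1.72 percentiles. Of these genes 12 were lower at both times and 5 higher, with IVL at -0.52 and -0.75, SPRR1B at -0.46 and -1.05 and S100A7 at -0.53 and -0.89. The median at 48 h argues against a programme lower as a whole at that time, and a part of it lower at both times stays open. The NRF2 target genes outside HMOX1 had medians of 0.029 and 0.11 over 24 genes, at the 96.6 and 96.8 percentiles. That is short of the highest 2.5% asked for beforehand, and whether HMOX1 moved with a wider NRF2 programme stays open.

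The basal keratins were lower with siLRRC26 and also lower at 72 h than at 48 h. Reading of 1 keratin by probes of its relatives is argued against as the whole cause, because keratins of both types were lower. The types share little sequence. The median difference was -0.65 for type II (of KRT5, KRT6A and KRT6B) and -0.70 for type I (of KRT14, KRT15, KRT16 and KRT17). The type II value is that of KRT6B, and both types were already seen to be lower when this check was chosen. Sharing within a type stays open. Cultures with siLRRC26 might have been further along the change from 48 h to 72 h: over the basal genes the median ratio of siRNA difference to time change was 0.75. Over the 500 other genes with the widest time change it was 0.095 (95% bootstrap bounds over genes 0.062 and 0.14). That is far under the 0.50 that this explanation needs, although the bounds reach past the 0.10 set beforehand as its limit. The 500 genes were picked for a wide time change, which can lower their ratio, and the basal genes were not. Of the 500, 308 differed with siLRRC26 in the direction of their time change. Genes are not independent, so the bounds do not measure the spread between cultures. Where 1 array stood apart, as for PHKA1 (-1.87 with siRNA, -1.82 with time), both changes are alike in size whatever the cause. Such genes were not left out and can blur the median, so a share of this explanation stays open. An effect of LRRC26 and an effect of the siRNA itself on the basal genes both remain untested.

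The interferon-stimulated genes were lower with siLRRC26 and shifted higher with time at the preset correlation. With an estimated correlation, which could hardly call any list here, neither was called by limma camera (adjusted p = 0.937 and 0.778). With no detection filter the shift with time was not called (adjusted p = 0.0991). The list median rose from 48 h to 72 h by 0.23 in siEGFP and by 0.12 in siLRRC26. A difference between the siRNAs as transfected RNA may account for this, since interferon-stimulated genes respond to double-stranded RNA. The siRNAs came from different suppliers, and with 1 siRNA per target an effect of LRRC26 and an effect of the siRNA cannot be told apart in these 4 arrays.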
